A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

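RNA of 3 untreated and 3 glycolaldehyde-treated yeast samples was measured on single-colour Agilent arrays (design 015072), which carry 7 spots for each of 6256 yeast probes, or 43792 non-control spots. Per the labels' protocols, 200 ng of total RNA was amplified and labelled with the dye Cy3. Per the file headers, the authors extracted each spot's intensity with Agilent Feature Extraction 11.0.1.1, as a green processed signal after background subtraction and detrending on a linear scale, with no normalization between arrays. R 3.0.2 is named in the submitters' processing notes without a role. The deposited value table of the series holds an intensity on a linear scale, uncentred, which is the plain mean of a probe's 7 processed signals on 1 array. Its column medians were 3545, 3346 and 4612 for untreated replicates 1 to 3 and 3307, 3373 and 5055 for glycolaldehyde replicates 1 to 3. No column of the table was left without a sample (0 unmapped). The other columns used, per the file headers, were the flags for outlier spots and for spots well above background, the saturation flag, and the median spot and background intensities.

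Groups come from the sample titles and the treatment entries. The free-text descriptions say the reverse for each of the 6 samples, and were not used. Which array belongs to which sample was taken first from the attachment of the scanner files, as planned. It was then taken from the value table, whose columns carry the sample's identifier and match the scanner files value by value. These are called the scanner-file record and the value-table record. The design written before the data were examined used the first; the second was brought in because the records disagree, and giving it the room in the text was decided after both results were known. Arrays were on 3 slides and scanned on 2 days. In the value-table record slide 1 held untreated replicate 1, slide 2 untreated replicate 2 and glycolaldehyde replicates 1 and 2, and slide 3 replicate 3 of both groups, which was also all of scan day 2.

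Control spots and outlier-marked spots were left out (0.614% to 0.964% of spots per array). The log2 processed signal minus the array's 75th percentile was averaged over the spots of a probe. A probe counted as well above background on an array when more than 0.5 of its spots did, and it was tested when this held on all 3 arrays of at least 1 group. Of the 6256 probes 5765 matched a gene in the reference name table (assembly R64), 5242 with a standard name; no coordinates were used because no genome was given. There were 6225 gene identifiers, and for the 29 with several probes the brightest probe was kept. Among these 29 the probes of 2 differed in sign, by at most 0.151, and those of FDH1, near background in untreated cells, differed by 0.66 in log2 change. No probe sequences were compared, so signal shared between near-identical genes was not separated.

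The arrays were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with treatment as the only term, two-sided tests and Benjamini-Hochberg adjusted p under 0.05; genes changed at least 2-fold also needed a log2 change of 1. SE is the moderated standard error of limma. In all, 32 gene lists were fixed before the data were examined, from general knowledge of yeast and of the treatment, with 5 further lists of strain, mating type and meiosis markers. They were tested with camera at the preset inter-gene correlation of 0.01, adjusted over the 32 lists. Of the listed names 2 were not on the array. Alternatives to the set test were camera with an estimated correlation and fry, whose directional p tests whether a list's genes move on balance one way and whose mixed p whether they change at all; neither compares a list with other genes. Named genes followed a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls among called genes with a standard name, above background on all 6 arrays and with no overlap between groups. It added up to 4 genes per direction that were above background in only one group, 12 genes named in advance (ADH1, SFA1, ADH6, ADH7, GRE2, GRE3, ALD6, GLO1, ZWF1, GSH1, SMT3 and UBI4), and the members with the largest changes in each list described. Of the genes this rule gives, 1 is not reported here.

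The replicate numbers are shared by the groups, so their pairing was checked on deviations from the group means over 5905 probes. In the value-table record the same-numbered arrays correlated with 0.361, 0.434 and 0.639, all above the limit of 0.1, so the numbers were taken to pair the samples. The reported counts, SE and p still come from the fit without a replicate term. The replicate block, run as an alternative, called 2250 genes up and 1720 down. Deviations from a group mean cancel out, so a shift shared by replicate 3 is enough to make the other pairs correlate. The pairing comes from these data: replicate 3 of both groups shares slide 3 and scan day 2, while replicates 1 and 2 were not told apart, since untreated replicate 1 correlated better with glycolaldehyde replicate 2 (0.569). In the scanner-file record the first pair correlated with -0.71, and the numbers do not pair the samples there. Replicates 1 and 2 of a group differed by more than the noise between spots: the median squared difference over the spot variance was 1.80 for untreated and 2.09 for glycolaldehyde, against 0.484 if spots alone differed. Repeat hybridisations of 1 RNA could also differ by more than spot noise, so this does not show separate cultures. They were kept as separate samples because the labels name them so, with a fit on their average as an alternative.

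Alternatives planned in advance were quantile normalization, median centring, normexp background correction (offset 50), no filter and a stricter filter on dim probes, slide as a fixed or random block (duplicateCorrelation, statmod 1.5.0), a replicate block, eBayes with trend and robust, the value table itself, the mean of a gene's probes, leaving out each array in turn, and an adjusted p under 0.01. Normexp used the median spot signal, since the files used here hold no mean spot signal. Alternatives added after seeing the data were the 4 arrays on which both records agree, the value-table record, scan day as a block, scan day 1 alone, and replicates 1 and 2 averaged with scan day as a block. The procedure was tested on simulated data with known changes in the value-table grouping, over 5944 genes. It recovered 28.79% of 66 genes changed by a log2 of 0.25, 93.94% of 66 changed by 0.5 and 100% of 65 changed by 1, and called 9 of 5709 unchanged genes. The simulated noise was independent between genes and arrays, with no effect of slide, scan day or replicate pair. Most simulated genes were unchanged, whereas 54.1% of genes were called in the real data. These shares therefore test the procedure and need not hold for the real arrays.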

Results

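Gene expression was measured in the budding yeast Saccharomyces cerevisiae strain BY4743, a laboratory strain of the S288C lineage, with and without glycolaldehyde. Glycolaldehyde is a small, reactive hydroxyaldehyde that also occurs in hydrolysates of plant biomass, where it slows yeast fermentation. Per the labels, the treated cells received 10 mM glycolaldehyde for 4 h at 30 °C in static culture in synthetic medium with 2% glucose, and the untreated cells were grown alike without it. The labels' growth entry reads anaerobic where the treatment protocol says static, so the supply of oxygen is not known. The growth protocol can also be read as giving the aldehyde to the overnight culture, so the full length of exposure is open. The labels name 3 untreated and 3 glycolaldehyde samples, with RNA prepared from 3 independent starter cultures, and each sample was hybridised to its own single-colour array. Between 5929 and 6070 yeast probes (94.8% to 97%) were well above background per array, and 0 spots were saturated. The number of arrays limits the precision of every value.

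The deposited records disagree on which array belongs to which sample. Each column of the authors' deposited value table equalled the mean spot signal of 1 scanner file at every probe (relative tolerance 1e-06), and for 3 of the 6 samples that file was the one attached to a different sample. The column of untreated replicate 3 equalled the file attached to glycolaldehyde replicate 2, the column of glycolaldehyde replicate 1 equalled the file of untreated replicate 3, and the column of glycolaldehyde replicate 2 equalled the file of glycolaldehyde replicate 1. As a result 2 arrays change group between the records and 4 keep it, 2 of them untreated and 2 glycolaldehyde. The comparison planned before the data were examined followed the scanner files as attached. It called 0 genes in limma (smallest adjusted p = 0.92), with 134 of 5924 genes at an unadjusted p under 0.05 where 296 would arise by chance. With camera's preset correlation 4 gene lists rose and 8 fell in that comparison, and 0 did with an estimated correlation. The gene values that follow use the grouping of the value table, which was chosen after the results of both groupings had been seen. The reason for it that does not rest on the results is that the table holds the authors' own processed values under each sample's identifier. The scanner files are attached to samples in the same way, so that reason does not show which record is right. Counts from the 4 arrays on which both records agree are given beside this grouping.

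**Figure D1:**
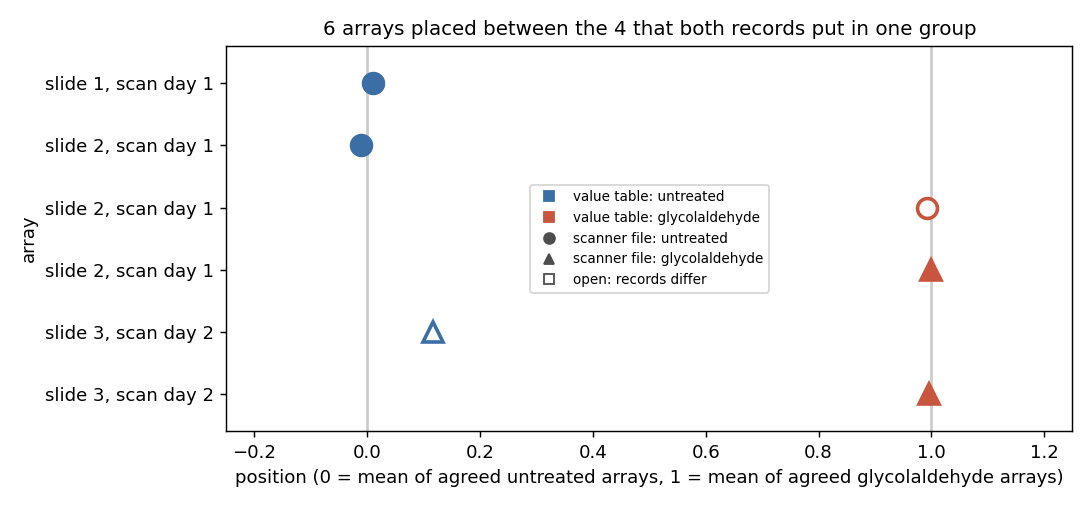
Each point is 1 array, placed on the x axis between the mean of the 2 agreed untreated arrays (0) and the mean of the 2 agreed glycolaldehyde arrays (1) over 5905 probes well above background on every array; colour gives the group in the value table, shape the group of the attached scanner file, and open symbols the arrays on which the records differ. The array attached as untreated replicate 3 lies at 0.992 and the array attached as glycolaldehyde replicate 2 at 0.116.

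The comparison asks which transcripts differ between cells with and without glycolaldehyde. In the value-table grouping, most genes of the proteasome were higher with glycolaldehyde, and most genes for the synthesis of purines and amino acids were lower. ADH7, an NADPH-dependent alcohol dehydrogenase, rose by 3.05 ± 0.06 on the log2 scale (SE, n = 3 per group), or 8.28-fold, and FLR1, a plasma membrane drug exporter, rose by 2.82 ± 0.07, or 7.06-fold. ADE17, an enzyme of the last steps of inosine monophosphate synthesis, fell by 3.40 ± 0.10, and ARG1, argininosuccinate synthetase, fell by 2.56 ± 0.07. Of 38 measured proteasome genes 36 rose and 0 fell, and of 18 genes of purine synthesis and one-carbon metabolism 17 fell and 0 rose. Signs are glycolaldehyde minus untreated as the titles and the treatment entries name the samples; the free-text descriptions say the reverse for every sample.

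Across the 5944 genes tested, 1824 rose and 1393 fell at an adjusted p under 0.05 in limma, and 81 rose and 105 fell at least 2-fold. In all 54.1% of the tested genes were called, which is the share to set beside the counts of list members. The 4 agreed arrays alone gave 1635 genes that rose and 1308 that fell, with 93 and 109 at least 2-fold, and 2638 of the 3217 genes were called in the same direction in both fits and 0 in opposite directions. Every glycolaldehyde array lay on the same side of every untreated array for 61.1% of the tested genes. Chance gives 10% for 3 against 3 only if all arrays are independent and the grouping was fixed before the results were seen. This grouping was chosen after both results had been seen, and replicates 1 and 2 of each group lay close together. The 10% is therefore not a benchmark for the 61.1%, and the share expected here was not worked out. Arrays were scanned on 2 days, and both groups were present on each. The changes within scan day 1 (2 arrays against 2) and within scan day 2 (1 against 1), which share no array, correlated across 5952 genes with r = 0.933, where genes are not independent replicates. Of the 4196 genes called within scan day 1 alone, 94.4% had the same sign on scan day 2. Replicates 1 and 2 of each group were far closer to each other (SD of log2 differences 0.0848 for untreated and 0.10 for glycolaldehyde) than either was to replicate 3 (0.18 to 0.203), which was scanned on the other day.

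The 8 largest rises among named genes above background on all 6 arrays, with no overlap between the groups, were those of ADH7, FLR1, AZR1, OYE3, AAD6, OSI1, AAD4 and GTT2. AZR1, a transporter of the major facilitator superfamily, rose by 2.60 ± 0.05, and OYE3, an NADPH oxidoreductase of the old yellow enzyme family, rose by 2.22 ± 0.07. AAD6 and AAD4, putative aryl-alcohol dehydrogenases, rose by 2.02 ± 0.19 and 1.93 ± 0.06. OSI1 rose by 1.94 ± 0.06, and GTT2, a glutathione transferase, rose by 1.83 ± 0.12. The largest adjusted p among these 8 was 0.00012, for AAD6. The AAD genes are near-identical in part, and signal shared between their probes was not separated here.

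The largest falls were those of ADE17, SNO1, ARG1, SHM2, GCV1, GCV2 and MEP2. SNO1, which acts with SNZ1 in vitamin B6 synthesis, fell by 2.75 ± 0.07, and SHM2, the cytosolic serine hydroxymethyltransferase, fell by 2.55 ± 0.07. Of the subunits of the mitochondrial glycine decarboxylase complex, GCV1 fell by 2.53 ± 0.08 and GCV2 fell by 2.51 ± 0.12. MEP2, a high-affinity ammonium permease, fell by 2.40 ± 0.06. The largest adjusted p among these 7 was 5.9e-06, for GCV2. AI3, a reading frame within an intron of the mitochondrial COX1 gene, was well above background on the 3 untreated arrays and on no glycolaldehyde array, and was at least 2.22-fold lower with glycolaldehyde (adjusted p = 0.00034). That bound sets the untreated mean against the higher, per array, of the probe's own signal and the lowest signal among probes well above background. It holds for the means over both scan days and is not reached on scan day 2. There the log2 change of AI3 was -0.80, against -1.58 within scan day 1.

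**Figure D2:**
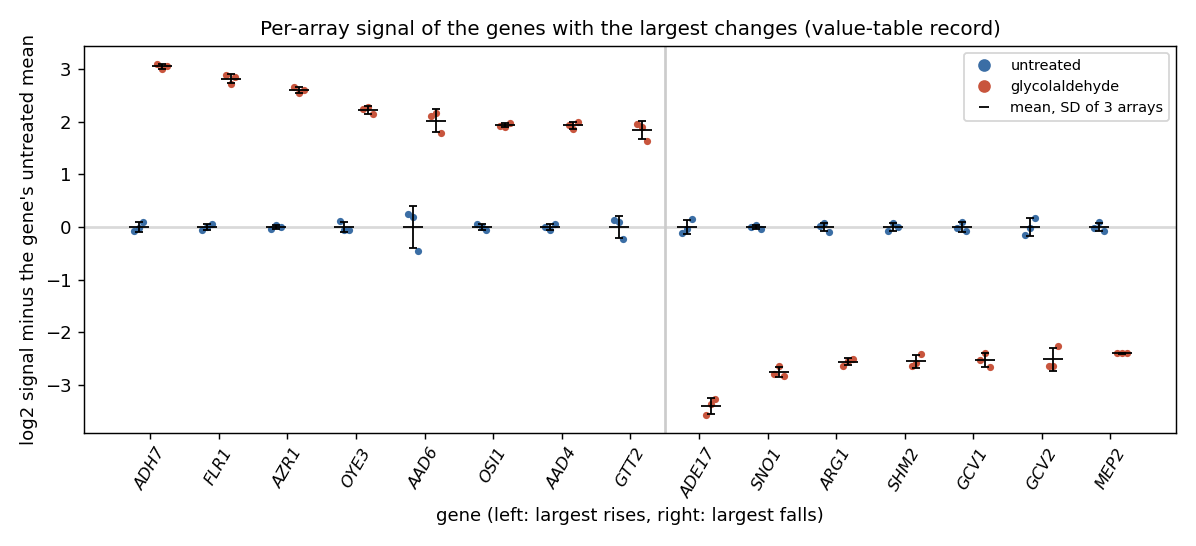
The y axis gives the log2 signal of 8 genes with the largest rises (left) and 7 with the largest falls (right), each minus the gene's untreated mean, in the value-table grouping; points are arrays and bars the mean ± SD of 3 arrays. The groups do not overlap for any of the 15 genes, and the smallest gap between them is 1.51, for GTT2.

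Genes that act on aldehydes and ketones moved both ways. Of 31 measured genes of aldehyde and ketone reduction and oxidation 17 rose, 7 fell and 7 did not pass, with a median log2 change of 0.17, and the list did not pass the set test (adjusted p = 0.109). SFA1, the glutathione-dependent formaldehyde dehydrogenase, and ADH6, an NADPH-dependent alcohol dehydrogenase, rose by 0.49 ± 0.05 and 0.50 ± 0.06, and the methylglyoxal and aldose reductases GRE2 and GRE3 rose by 1.38 ± 0.07 and 0.53 ± 0.10. GLO1, the lactoylglutathione lyase of methylglyoxal detoxification, rose by 0.37 ± 0.05. ADH5, an alcohol dehydrogenase isozyme, fell by 2.12 ± 0.06. The main fermentative alcohol dehydrogenase ADH1 had a log2 change of -0.07 ± 0.17 and the cytosolic aldehyde dehydrogenase ALD6 one of 0.00 ± 0.08, and neither passed (adjusted p = 0.741 and 0.973).

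Proteasome genes rose together, with a median log2 change of 0.74 over 38 genes (0.76 within scan day 1 and 0.73 within scan day 2). PRE1 and PRE8 of the core particle rose by 0.99 ± 0.05 and 0.96 ± 0.07, and RPT2 and RPN13 of the regulatory particle by 0.96 ± 0.08 and 0.95 ± 0.09. The list passed camera with the preset correlation (adjusted p = 5.7e-14), and had an adjusted p = 0.129 with an estimated correlation. In the ubiquitin system 20 of 28 genes rose and 2 fell (median 0.35; adjusted p = 0.000447, and 0.111 with an estimated correlation). Among them UBI4, which encodes polyubiquitin, rose by 1.23 ± 0.05, and UFD1 and NPL4, partners of Cdc48, rose by 0.98 ± 0.06 and 0.91 ± 0.05. In the SUMO pathway 2 of 14 genes rose and 5 fell (median -0.13; adjusted p = 0.0742, 0.449 with an estimated correlation, and 0.0425 in the 4 agreed arrays with the preset one); MMS21, a SUMO ligase, fell by 0.50 ± 0.07, and SMT3, which encodes SUMO itself, had a log2 change of -0.02 ± 0.08 (adjusted p = 0.844).

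Of 28 heat shock chaperone genes 24 rose and 2 fell (median 0.62, and 0.62 and 0.58 within scan days 1 and 2; adjusted p = 6.77e-07, and 0.226 with an estimated correlation). BTN2, a protein-sorting factor, rose by 1.49 ± 0.06, the Hsp90 co-chaperones HCH1 and AHA1 by 1.46 ± 0.07 and 1.40 ± 0.07, and HSP82 by 1.24 ± 0.08. In the list of the unfolded protein response and folding in the endoplasmic reticulum 15 of 22 genes rose and 3 fell (median 0.27; adjusted p = 0.0157, and 0.284 with an estimated correlation), and the list did not pass with replicates 1 and 2 averaged and scan day as a block (adjusted p = 0.0645). The oxidase ERO1 and the chaperone KAR2 rose by 0.90 ± 0.06 and 0.85 ± 0.08, while HAC1, the transcription factor of that response, fell by 0.67 ± 0.11. Autophagy and vacuolar protease genes did not pass as a list (11 of 24 rose, 6 fell, adjusted p = 0.331), and ATG8 rose by 0.73 ± 0.07.

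In the list of oxidative stress and thiol redox genes 18 of 32 rose and 2 fell (median 0.27; adjusted p = 0.00284, and 0.171 with an estimated correlation). Besides OYE3 and GTT2, the mitochondrial peroxiredoxin PRX1 rose by 1.00 ± 0.06 and YCF1, a vacuolar transporter of glutathione conjugates, by 0.87 ± 0.05. GSH1, the first enzyme of glutathione synthesis, rose by 0.35 ± 0.06. In the pentose phosphate pathway 4 of 11 genes rose and 2 fell (adjusted p = 0.577); ZWF1, glucose-6-phosphate dehydrogenase, rose by 0.39 ± 0.06 and the transketolase TKL1 fell by 0.48 ± 0.07. Of 23 DNA damage response genes 10 rose and 1 fell (median 0.15; adjusted p = 0.00557, and 0.233 with an estimated correlation). The 12 that did not pass included HUG1 and the ribonucleotide reductase genes RNR1 to RNR4, with log2 changes between -0.15 (RNR1) and 0.15 (RNR2). MAG1, a DNA glycosylase of alkylated bases, rose by 1.59 ± 0.07, and DDI2 and DDI3, which are near-identical copies whose signals were not separated, by 1.00 ± 0.06 and 1.02 ± 0.06. Of 24 multidrug resistance transport genes 10 rose and 5 fell (adjusted p = 0.313): FLR1 rose, and the exporters QDR3 and AQR1 fell by 1.67 ± 0.05 and 1.39 ± 0.05.

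The falls were largest in nitrogen and nucleotide metabolism. Purine and one-carbon genes had a median log2 change of -1.55 over 18 genes (-1.57 within scan day 1 and -1.49 within scan day 2; adjusted p = 6.27e-14, and 0.114 with an estimated correlation). Of 51 genes of Gcn4-type amino acid biosynthesis 44 fell and 1 rose (median -0.67, and -0.71 and -0.60 within scan days 1 and 2; adjusted p = 1.6e-17, and 0.111 with an estimated correlation). HIS4 of histidine synthesis fell by 2.02 ± 0.06 and ARG4, argininosuccinate lyase, fell by 1.94 ± 0.06. Of 25 genes under nitrogen catabolite repression 20 fell and 1 rose (median -1.12, and -1.09 and -1.14 within scan days 1 and 2; adjusted p = 9.69e-11, and 0.0766 with an estimated correlation). The proline permease PUT4 fell by 1.89 ± 0.06 and the urea permease DUR3 fell by 1.84 ± 0.08. Of 26 genes of methionine synthesis and sulfate assimilation 12 fell and 2 rose (median -0.15; adjusted p = 0.00557, and 0.283 with an estimated correlation). STR3, MET13 and MET6, which act in homocysteine and methionine synthesis, fell by 1.35 ± 0.11, 1.26 ± 0.07 and 1.20 ± 0.08.

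**Figure D3:**
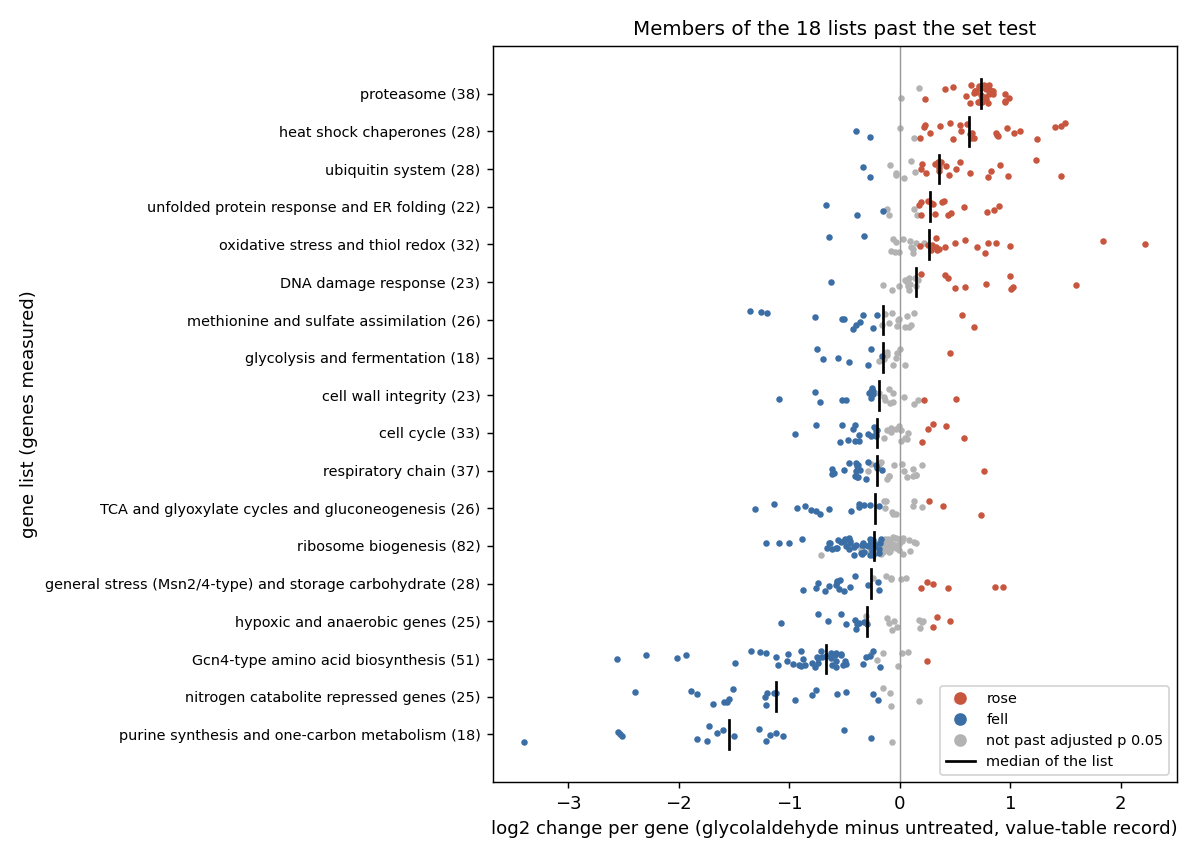
Each point is 1 gene of the 18 lists past the set test, with its log2 change (glycolaldehyde minus untreated, value-table grouping) on the x axis and the number of genes measured beside each list; red genes rose, blue genes fell, grey genes did not pass, and black bars are list medians. Medians run from -1.55 for purine synthesis and one-carbon metabolism to 0.74 for the proteasome.

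Among growth-related genes, 43 of 82 ribosome biogenesis genes fell and 0 rose (median -0.23; adjusted p = 1.94e-08, and 0.283 with an estimated correlation). The box C/D ribonucleoprotein genes NOP56 and NOP58 fell by 1.21 ± 0.19 and 1.00 ± 0.12, and the helicase gene DBP2 fell by 1.09 ± 0.09. Cytosolic ribosomal protein genes had a median of 0.01 over 137 genes, of which 7 rose and 12 fell (adjusted p = 0.362, and 0.92 with an estimated correlation), while in the 4 agreed arrays the list passed with the preset correlation, downwards (median -0.07, adjusted p = 0.019). Over all 6 arrays RPS9A fell by 0.83 ± 0.07. Of 33 cell cycle genes 17 fell and 5 rose (median -0.20; adjusted p = 0.00557, and 0.129 with an estimated correlation), and with replicates 1 and 2 averaged and scan day as a block the list did not pass (adjusted p = 0.0543). CLB6 had a log2 change of -0.95 ± 0.09 and CLN1 one of -0.76 ± 0.13. Among 11 histone genes only the centromeric variant CSE4 passed, and it rose by 0.25 ± 0.08 (list adjusted p = 0.893). In the 4 agreed arrays 0 histone genes rose and 0 fell.

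In carbon metabolism, 7 of 18 glycolysis and fermentation genes fell and 1 rose (median -0.15; adjusted p = 0.01, and 0.449 with an estimated correlation). The phosphofructokinase subunits PFK1 and PFK2 fell by 0.75 ± 0.07 and 0.69 ± 0.06, and this list was lost with quantile normalization (adjusted p = 0.078) and with replicates 1 and 2 averaged and scan day as a block (0.0699). Of 26 genes of the TCA and glyoxylate cycles and gluconeogenesis 14 fell and 3 rose (median -0.23; adjusted p = 0.000643, and 0.111 with an estimated correlation). The pyruvate carboxylase gene PYC2 fell by 1.31 ± 0.10 and the peroxisomal citrate synthase gene CIT2 fell by 1.14 ± 0.08. Of 37 respiratory chain genes 18 fell and 1 rose (median -0.21; adjusted p = 0.000447, and 0.145 with an estimated correlation). ATP1 fell by 0.61 ± 0.05, and the gene that rose was CYC1, cytochrome c isoform 1, by 0.76 ± 0.06. Of 19 hexose transporter genes 11 rose and 1 fell (median 0.33, adjusted p = 0.082); HXT9 rose by 1.27 ± 0.06, and the glucose sensor gene RGT2 fell by 0.97 ± 0.05. In the glycerol and osmotic stress list 4 of 18 genes rose and 5 fell (adjusted p = 0.885); GPD2 and GPD1, the glycerol-3-phosphate dehydrogenases, fell by 1.80 ± 0.10 and 0.66 ± 0.07.

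General stress genes of the Msn2/4 type and storage carbohydrate genes fell more often than they rose. Of 28 genes 16 fell and 6 rose (median -0.26; adjusted p = 0.00557, and 0.284 with an estimated correlation); TSL1 of trehalose synthesis fell by 0.76 ± 0.07, and the small heat shock protein gene HSP12 rose by 0.93 ± 0.09. Of 23 cell wall integrity genes 11 fell and 2 rose (median -0.19; adjusted p = 0.00296, and 0.226 with an estimated correlation), and PIR3 fell by 1.1 ± 0.08. Of 25 hypoxic and anaerobic genes 11 fell and 3 rose (median -0.29; adjusted p = 0.0281, and 0.449 with an estimated correlation). That list did not pass in the 4 agreed arrays (adjusted p = 0.197), without untreated replicate 3 (0.118) or without glycolaldehyde replicate 1 (0.0581). In the agreed arrays 8 of its genes fell and 7 rose, with a median of -0.116. FET4, an iron transporter of low affinity, fell by 1.08 ± 0.06.

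The remaining lists did not pass the set test on all 6 arrays. In the thiamine and vitamin B6 list 12 of 22 genes rose and 2 fell (median 0.29; adjusted p = 0.0679, 0.233 with an estimated correlation, and 0.0425 in the 4 agreed arrays with the preset one), and the 2 that fell were SNO1 and SNZ1, which fell by 2.75 ± 0.07 and 2.13 ± 0.07. In the phosphate regulon list 2 of 18 genes rose and 8 fell (adjusted p = 0.0668); PHM6 fell by 1.12 ± 0.10, and CTF19, a kinetochore gene that this list also held, fell by 0.58 ± 0.11. The iron regulon list had 7 of 25 genes that rose and 7 that fell (adjusted p = 0.59), among them the siderophore transporter SIT1, which fell by 1.27 ± 0.06. Ergosterol synthesis had 5 of 25 genes that rose and 7 that fell (adjusted p = 0.45), with ERG1 falling by 0.49 ± 0.06. Copper and zinc homeostasis had 4 of 18 that rose and 4 that fell (adjusted p = 0.927), with CCS1 rising by 0.54 ± 0.08. Median and set test differed in sign for 4 lists, namely cytosolic ribosomal proteins, the iron regulon, glycerol and osmotic stress, and copper and zinc homeostasis, and the median and the mean for the first 3 of these.

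In total 6 of the 32 lists rose and 12 fell with camera's preset correlation, and 0 passed with an estimated correlation (smallest adjusted p = 0.0766). A higher correlation does not account for every one of these losses. The estimate was 0.00932 for the nitrogen list, under the preset 0.01. It was -0.0145, -0.0103 and -0.0196 for the ubiquitin, TCA and cell cycle lists. In the other called lists it was above the preset, up to 0.34 for glycolysis. All 18 lists called with the preset correlation had medians of the same sign within each scan day, within slide 2 and in the 4 agreed arrays. These are parts of the 6 arrays that picked the lists, so some of that agreement was built in. Scan day as a block left every median as it was, since the groups are balanced over the days, so it tests no sign. Of the 18, 17 also passed in the agreed arrays. There 3 further lists passed with the preset correlation (the SUMO pathway, cytosolic ribosomal proteins, and thiamine and vitamin B6). Adjusted over the list alone, the counts were the same for 23 lists. For the other 9 they were 19 risen and 2 fallen for oxidative stress, 1 and 45 for Gcn4-type amino acid biosynthesis, 6 and 17 for general stress, 16 and 3 for the unfolded protein response, 0 and 3 for cytosolic ribosomal proteins, 12 and 2 for hexose transporters, 4 and 14 for the TCA list, 13 and 2 for thiamine and vitamin B6, and 0 and 0 for histones.

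The labels call BY4743 haploid, while the strain is commonly a diploid deleted for HIS3, LEU2 and URA3. HIS3, LEU2 and URA3 were not well above background on any of the 6 arrays, while LYS2 and MET17 were on all 6. All 7 genes specific to a cells, 4 specific to alpha cells and 11 haploid-specific genes were also well above background on all arrays. So were 94.8% to 97% of all probes per array, so that call says little about expression. Their median levels were low, at log2 values of -5.58, -4.7 and -4.58 relative to the array's 75th percentile. Neither mating type set was high. The highest percentile rank of level was 26.6 among the a-specific genes (STE6) and 25.7 among the alpha-specific ones (SAG1). The pheromone genes MFA1 and MF(ALPHA)1 lay at 10.6 and 13.1. A haploid culture of 1 mating type would express 1 of these sets, so the values argue against such a culture. Haploid-specific genes reached 59.1 (AMN1), and ploidy itself was not measured. Of the a-specific genes 4 rose and 0 fell with glycolaldehyde, and of the alpha-specific genes 1 rose and 2 fell, with the pheromone gene MF(ALPHA)1 at a log2 change of -1.02 (adjusted p = 3.7e-05). Of the haploid-specific genes 5 rose and 1 fell. Of 14 meiosis and sporulation genes 7 rose and 1 fell, and the genes with the largest values were DMC1 and NDT80 at log2 changes of 1.1 and 0.95. Of the deletion markers, LYS2 fell by 1.38 and MET17 fell by 0.29. Adjusted over the list alone, each of these counts was the same.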

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

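The tests with the value-table record, the 4 agreed arrays, scan day and averaged replicates were chosen only after the data had been seen. With the value-table record, the counts of genes stayed within 1.5 times the reported ones under every setting run except normexp, which gave 48 genes up at least 2-fold in place of 81, and the scanner-file record, which gave 0, 0, 0 and 0 in place of 1824, 1393, 81 and 105 because 2 arrays change group; the cause of the normexp count was not tested. The 25 called genes of the named set kept their sign and call in all 524 values under the other settings, and in 24 values with the scanner-file record they kept the sign and lost the call. With the scanner-file record, the value table itself gave 1761, 1397, 81 and 108 genes and the value-table record 1824, 1393, 81 and 105, in place of 0, because both regroup the arrays. With the replicate block the value-table record gave 2250 genes up, 1720 down and 6 and 12 lists, so it ended no gene call and moved no count by over 1.5 times; the scanner-file record gave 0 genes up and 0 down with the block. Counts of called lists depended on the choice of set test, a setting with no counterpart for genes. For the value-table record, 6 lists up and 12 down became 0 and 0 with an estimated correlation, and 12 up with fry's directional test. For the scanner-file record, 4 up and 8 down became 0 and 0 with an estimated correlation, 0 and 0 with fry, 5 down with quantile normalization and 2 up with slide as a random block, and leaving out one array at a time gave 0 to 7 up and 3 to 11 down; the cause was not tested. Of 378 values of the 18 called lists under other fits of the genes, 371 stayed past the threshold and 7 did not, for glycolysis, hypoxic genes, the unfolded protein response and the cell cycle. Signs that reversed belonged to results that had not passed their test, except for hypoxic genes, which fell with the value-table record (-0.293) and reversed with the scanner-file record. The gene ALD6 (0.0037) took log2 changes of -0.0329 with median centring, -0.00396 with normexp, -0.00114 with the value table, -0.0113 with the agreed arrays, -0.00456 with scan day 1 alone and -0.0188 with the scanner-file record, and -0.0416 to 0.0874 when one array was left out. The gene SMT3 took 0.0603 with the agreed arrays, 0.0409 with scan day 1 alone, 0.101 with the scanner-file record and -0.0704 to 0.0591 when one array was left out, and the gene ADH1 took -0.212 to 0.10 there. Medians at a reversed set-test direction were 0.0599 (quantile) and 0.0554 (scan day 1 alone) for the list cytosolic ribosomal proteins, and 0.0409 (normexp), 0.0428 (agreed arrays), 0.063 (scan day 1 alone), 0.0422 (fry) and 0.0246 (scanner-file record) for the list copper and zinc homeostasis, and -0.00743 (agreed arrays) and -0.0576 (scanner-file record) for the list histones. When one array was left out, these 3 medians took -0.0335 to 0.0815, 0.0276 to 0.0483 and -0.00913 to 0.0852. With the scanner-file record they were also 0.0233 for hypoxic genes, 0.0355 for ergosterol, 0.0222 for iron and -0.00829 for glycerol; the causes were not tested.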

Other observations

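The mitochondrial genes, FDH1, SOR1 and SOR2 and the tests on slides, splits, scaling, scan day and slowed growth in this part were chosen only after the results had been seen. Of 19 tested genes and reading frames on the mitochondrial genome, which no list covered and no set test was run on, 13 fell, 0 rose and 6 did not pass in the value-table grouping (median log2 change -0.58). They are not all separate transcripts, since AI1 to AI5 lie within COX1 and BI2 and BI3 within COB. Of the 13, 11 were also called in the 4 agreed arrays; ATP8 and COX3 were not. COX1, a core subunit of cytochrome c oxidase, fell by 1.95 ± 0.18 (SE, n = 3 per group; adjusted p in limma = 0.00012), and it fell by 2.13 within scan day 1 and by 1.60 within scan day 2. ATP6 and COB, of ATP synthase and of complex III, fell by 0.74 ± 0.10 and 0.51 ± 0.10, whereas OLI1, another ATP synthase subunit, had a log2 change of -0.02 ± 0.10 (adjusted p = 0.885). In the pair of arrays of scan day 2, 16 of the 19 were lower.

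FDH1, an NAD-dependent formate dehydrogenase gene outside the named set, rose (adjusted p = 2.3e-05), but it was well above background on all 3 glycolaldehyde arrays and on only 1 of the 3 untreated arrays, so no size is given. SOR1 and SOR2 are near-identical sorbitol dehydrogenase genes whose signals were not separated. SOR1 rose by 1.78 ± 0.15, and SOR2 also rose, from a level above background on only 1 untreated array.

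In the scanner-file record 2 arrays lie with the other group. On the axis from untreated (0) to treated (1) set by the 4 agreed arrays, the array attached as untreated replicate 3 lies 0.876 above the array attached as glycolaldehyde replicate 2. A slide effect is argued against, because on axes set by the agreed arrays of the other slides alone the arrays of slide 2 span 0.914 and those of slide 3 span 0.857, where a slide effect would hold each within 0.5. Scanner files attached to the wrong samples and cultures that truly differed cannot be told apart by expression, since the array values are the same under either record.

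Of the 10 splits of the 6 arrays into 3 and 3, the value-table split called 3217 genes and 186 at least 2-fold, and the highest of the other 9 called 0 and 0 (1 split as large, in each case). The 10 splits cannot give a share under 0.05, since 0.1 is the smallest. Each of the other 9 splits mixes arrays of both value-table groups, which puts the group difference into its residual spread. They had 2 to 252 genes at an unadjusted p under 0.05 in limma, where about 297 would arise by chance. Low gene counts were bound to follow there, so the contrast does not show which record is right. Among the 4 splits that part all 3 replicate pairs, the highest of the other 3 called 0 genes and 15 lists. The scanner-file split called 0 genes, which all 10 splits reach, and the highest other called 3217. Gene lists did not separate in this way: the value-table split called 18 lists and the highest of the other 9 also 18 (2 splits as large), in a split that follows no slide, scan day or record and parts 1 of the 3 pairs, and the lowest called 8. With the preset correlation, counts of called lists therefore carry little weight here. The counts of their members are to be read beside the 54.1% of all tested genes that were called, 1824 up and 1393 down. The iron regulon list, for one, with 7 of 25 genes up and 7 down, lies near that share. Members of a list can also move together, so their counts are not independent.

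The amino acid, purine and nitrogen lists fell together, with 81 of 94 genes lower and 2 higher in the value-table grouping, although with an estimated correlation none of the lists passed (adjusted p = 0.111, 0.114 and 0.0766). The fall did not depend on the scaling used: the median over the 3 lists was at most -0.838 under median and quantile scaling. The median over all genes was 0.0378 as reported, 0.015 with quantile and 0.00117 with median scaling. Scalings that differ so little could not have brought the fall near 0. Within either scan day the median over the 3 lists was at most -0.755. Both groups were present on each day, so a day effect shared by the groups cancels in any case. The 3 lists were also picked from these same arrays. A general response of slowed growth stays open, since the lists it would move went different ways. The general stress list, which it would raise, had a median of -0.262 (95% bootstrap interval -0.549 to -0.0769), and 16 of its genes fell and 6 rose. Cytosolic ribosomal protein genes, which it would lower, had a median of 0.00829 (interval -0.0126 to 0.0243), but one of -0.0678 in the 4 agreed arrays. Such intervals describe the spread over genes, which can move together, and not over arrays. On the other side, 43 of 82 ribosome biogenesis genes fell and 0 rose, and 24 of 28 heat shock chaperone genes rose. Whether the fall follows from glycolaldehyde itself was not tested.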
